A study of Mus musculus with 2 samples.

How the data were processed

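Total RNA was extracted with TRIzol from 2 suspension cultures of mouse ES cells, and libraries were made with an Illumina TruSeq RNA kit and sequenced on a NextSeq 500, per the labels' protocols. One culture had no dox and the other had dox, both labelled 36 h, and the groups were taken from the agent given for each sample. Reads were processed with bcl2fastq, Bowtie2 and RSEM against the mouse build mm10, per the submitters' processing notes. The versions, the gene annotation, the normalization and the filter on genes are not given in the sources used here.

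The deposited table gave 14261 rows with a gene symbol and 1 value for each library. These deposited values were handled as a score on a count scale, taken to be normalized and rounded by the authors, and not as read counts. This was inferred from the values themselves: both libraries had quartiles of 14, 62 and 184, and 75.5% of the sorted positions held exactly equal values (tolerance 0). In each library the highest value, 14907, was shared by 10 genes, the next set ran from 6787 to 6778 and the third from 5344 to 5325. Such sets are what full-quantile normalization within and between libraries over 10 classes of genes gives, but no source used here states that step. The property that formed such classes was not identified. With transcripts divided into 10 bins of equal size, each set of 10 genes drew on a mean of 6.40 and 6.60 GC bins without and with dox, and on 6.05 and 6.35 length bins, against 6.51 by chance. On such a scale a value reflects the rank of a gene within its class, the depth of a library is not kept, and a gene that leaves the highest set lets another enter it. No count model was used. Values of 0 in both libraries stood in 629 rows, in 1372 rows without dox and in 857 with dox. Symbols that a spreadsheet had turned into dates stood in 21 rows and were not named, and 2 symbols stood on more than 1 row. Ribosomal RNA and mitochondrial genome transcripts were not analysed here. No other column of sample values was left unused (0).

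The log2 ratio of each gene was log2 of the value with dox plus a pseudocount of 10, over the value without dox plus 10. Genes entered where the larger of both values was at least 50, which left 8547 genes. A gene was counted as higher or lower at a ratio of 2-fold or more, a description of these 2 libraries. With 1 library per group no test, p-value or SD was computed. The pseudocount, floor, threshold, gene lists and alternatives were fixed before the data were examined, for the case of count values normalized by the authors.

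For 31 gene lists with 730 members, covering pluripotency, lineages, AP-1, adhesion, signalling, stress, metabolism and markers of other cell types, the median log2 ratio of the members at or above the floor was computed. Lists with at least 5 such members were set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. A second set of random lists was matched on expression in 10 bins and on transcript length in 5. Intervals of list medians and of rho came from 2000 and 500 bootstrap draws over genes, at 95%. They describe the spread over genes, not over cultures.

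Genes named in the text were Jun, the 15 highest and the 15 lowest log2 ratios among the 3118 genes whose larger value was at least 250, 5 times the floor, and up to 4 genes per list. In each list these were members past 2-fold, otherwise the members with the largest values. Where more passed, those with the largest values were mostly taken, a choice made after the data were seen. Some genes that this rule takes are not reported here by name. Clone-style symbols were counted and not named, except where the text says so.

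Symbols were matched to GENCODE M21 on GRCm38, the same assembly as mm10, which gave coordinates, gene types and the length of the longest transcript. Of the 14259 distinct symbols 14139 matched (99.2%), and 8472 genes at or above the floor (99.1%) had a length. The trend of log2 ratio on length was removed with lowess (fraction 0.3). Transcripts sharing sequence with Gm38312 were sought with BLAST 2.17.0, keeping alignments of at least 1000 nt. The steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

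The steps were tested on simulated data drawn on the 14261 genes for the comparison of dox with no dox, with 200 genes changed by 4-fold. Of the simulated 4-fold higher genes 98% were called, of the 4-fold lower genes 100%, and of the unchanged genes 0.35%. The noise between the simulated libraries was chosen, since that of the real libraries is unknown. Changed genes were drawn only from means well above the floor, and no length trend was put in. These rates therefore check the steps and are not error rates of the calls made here. A list shifted by 1 on the log2 scale had the percentile 100, and 3.5% of unchanged lists lay outside percentiles 2.5 to 97.5. The alternatives were a median log2 ratio set to 0, libraries scaled to the same total, pseudocounts of 1 and 50, no floor, a floor of 250, thresholds of 1.5-fold and 4-fold, and lists without members of other lists. Removing the length trend, leaving out genes at 0 and taking gene families with no floor were added after the data were seen.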

Results

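Gene expression was measured by RNA-seq in 2 cultures of mouse embryonic stem (ES) cells, labelled TRE-ESC, that were kept in suspension in dishes of low adsorption. The medium was N2B27 with 2i, a pair of kinase inhibitors, and LIF, a cytokine, which together hold mouse ES cells in the naive pluripotent state. One culture received doxycycline (dox), a drug widely used to switch on tetracycline-controlled transgenes, and the other received none, and both were labelled 36 h. There was 1 library per group, so there are no replicates, no test was made between the groups and no value has a spread between cultures. Intervals, where given, describe the spread over genes. The deposited table gave 14261 rows of whole numbers on a normalized count scale in which both libraries had the same quartiles of 14, 62 and 184. Its sums of 2704318 without dox and 2709923 with dox were therefore not taken as sequencing depth, which is unknown for each library, and no counting interval is given. Folds are ratios of the values after a pseudocount of 10 was added to each, which understates the difference of genes with low values.

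The first comparison asked whether the library labelled with dox carried more Jun RNA, since the series concerns differentiation induced by c-Jun, the product of Jun and a subunit of the transcription factor AP-1. Jun was listed at 55 without dox and at 3821 with dox, 58.9-fold higher, which is a log2 ratio of 5.88. Its rank by value among all rows went from 7444 to 45. Among the 3118 genes whose larger value was at least 250, it had the rank 4 by log2 ratio. Jun is a gene without introns on the minus strand of chromosome 4, from 95049034 to 95052222 in the build GRCm38. The table gave 1 value per gene, so RNA from a transgene and from the chromosomal copy could not be separated. With a pseudocount of 50 its log2 ratio was 5.20.

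The second comparison asked which genes differed between the libraries with and without dox in suspension. Among the genes highest with dox were Gsn, Col7a1, Flnc and Jun, and among the lowest were Lars2, Khdc3, Bhmt and Aqp3. Of 8547 genes whose larger value was at least 50, 789 were at least 2-fold higher with dox and 469 at least 2-fold lower, so 62.7% of these calls were higher. The other 85.3% of genes were within 2-fold, and the median log2 ratio was −0.08. At a 4-fold threshold 266 genes were higher and 55 lower, whereas at 1.5-fold 1425 were higher and 1511 lower. Across genes the log2 ratio rose with transcript length (Spearman rho 0.27 over 8472 genes, which are not independent replicates). With that trend removed, 737 genes were higher and 425 lower.

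**Figure D1:**
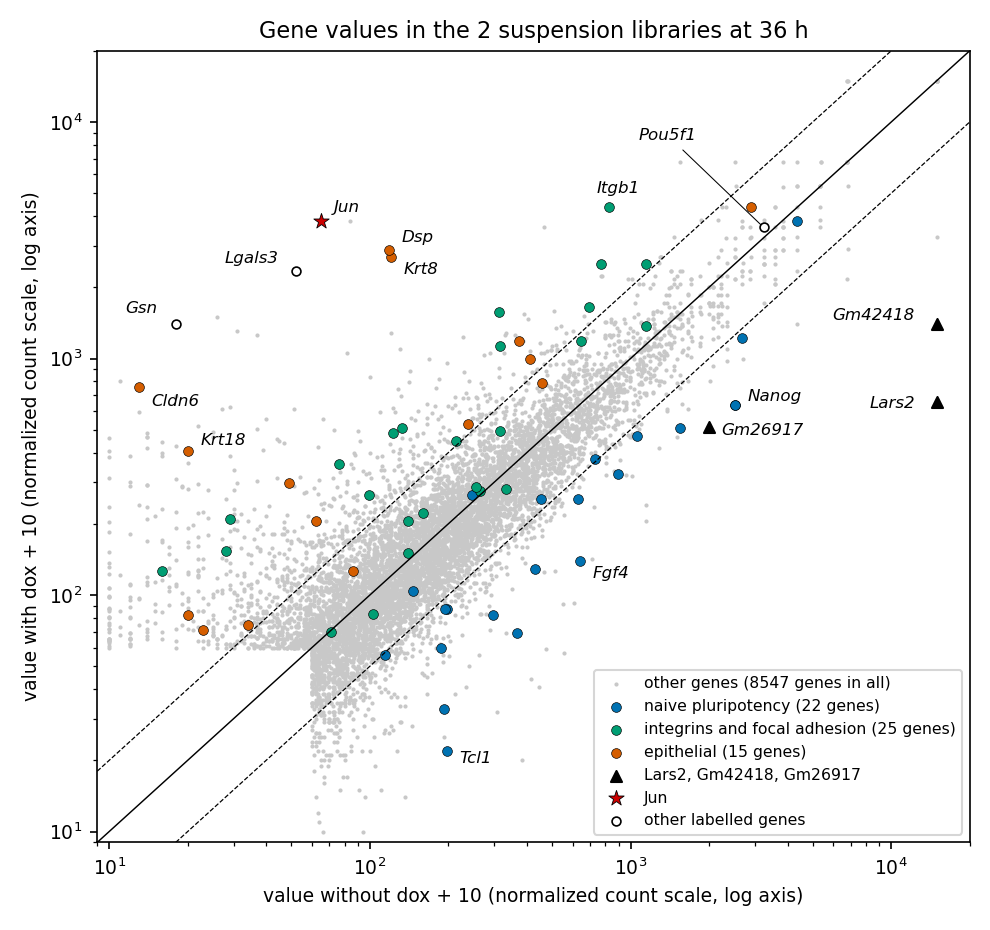
Values of 8547 genes in the library without dox (x axis) and with dox (y axis), each plus 10, on log axes in normalized count units, with 1 library per group. The solid line marks equal values and the dashed lines a 2-fold difference; Jun stands at 55 and 3821, naive pluripotency genes (blue) lie mostly below the lower dashed line, and Lars2, Gm42418 and Gm26917 (triangles) lie below it too.

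By the rule fixed for naming genes, the 15 highest log2 ratios began with Gsn, which encodes the actin-severing protein gelsolin and stood at 8 without dox and 1392 with dox. Gsn lies on chromosome 2 from 35256380 to 35307892. The collagen gene Col7a1 stood at 1 and 795, and Col5a3, another collagen gene, at 3 and 586. Flnc, which encodes the actin cross-linker filamin C, stood at 3 and 760. Cldn6, a tight junction claudin gene, stood at 3 and 749, and the transglutaminase gene Tgm2 at 16 and 1491. Peg10, an imprinted gene derived from a retrotransposon, had the same value as Jun with dox, 3821, from 74 without. Lgals3, which encodes galectin-3, stood at 42 and 2326, and the calcium-binding S100a6 at 21 and 1293. Msln, the mesothelin gene, stood at 8 and 684, and Krt19, a keratin gene of simple epithelia, at 4 and 474. The neuropeptide gene Gal, the metalloproteinase inhibitor gene Timp2 and the keratin gene Krt7 were listed at 0 without dox and at 451, 398 and 374 with dox. Ratios this close to 0 depend on the pseudocount. The log2 ratio of Col7a1 was 6.19, and 4.05 with a pseudocount of 50, while that of Col5a3 went from 5.52 to 3.58 and that of Krt19 from 5.11 to 3.28. The order of the genes changes as well. With a pseudocount of 1 Gsn had 7.27, below Gal at 8.82, and with 50 it had 4.64, below Jun at 5.20.

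The lowest log2 ratio, −4.51, was that of Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, at 14907 without dox and 646 with dox. Lars2 lies on chromosome 9 from 123366927 to 123462666 and is known to collect reads of ribosomal RNA. Gm42418 and Gm26917, noncoding genes annotated on chromosome 17 from 39846958 to 39848788 and from 39843013 to 39846341 and known for the same, were singled out after their values were seen. They were also lower with dox, at 14907 and 1393 and at 1990 and 505. Khdc3, a gene of a maternal complex of the oocyte, stood at 435 and 31, the methyltransferase gene Bhmt at 548 and 47, and the water channel gene Aqp3 at 404 and 34. Lefty2, which encodes a Nodal antagonist, went from 1139 without dox to 196 with dox, 5.58-fold lower. Tdgf1, which encodes a Nodal co-receptor, stood at 1137 and 231. Nr5a2, a nuclear receptor gene of naive cells, stood at 358 and 59, and the growth factor gene Fgf4 at 631 and 129. The 15 lowest further held Igfbp2 at 464 and 49, Hsd17b14 at 598 and 83, the homeobox gene Crxos at 539 and 82, and the uridine phosphorylase gene Upp1 at 703 and 132. They also held the amino acid transporter gene Slc7a3 at 252 and 46, Rnd3 at 278 and 61 and Prps1 at 502 and 117. Of the 15 highest genes 7 stood in a gene list fixed beforehand, and of the 15 lowest 5 did. No clone-style name ranked above the 15th highest, and 5 ranked below the 15th lowest.

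Naive pluripotency genes were lower with dox as a group. Of 22 measured members 17 were at least 2-fold lower and 0 were higher, with a median log2 ratio of −1.39, and 0 of 10000 random lists of the same size matched on expression had a median as low. Nanog, a transcription factor gene of the naive state, stood at 2508 without dox and 623 with dox. Esrrb stood at 1531 and 500, Tfcp2l1 at 2672 and 1208, and the threonine dehydrogenase gene Tdh at 2512 and 628. The list of core pluripotency genes, which are also active outside the naive state, had 6 of 17 members lower and 1 higher, with a median of −0.81 that 0 of the 10000 random lists reached. Over its 13 members with a value of at least 250 this median was −0.47. Its members Utf1, at 270 and 73, and Sall4, at 590 and 287, were lower, as was Tdgf1, and the adhesion gene Epcam was higher, at 228 and 520. Chosen after their values were seen, Pou5f1, which encodes Oct4, stood at 3230 and 3572, Sox2 at 1042 and 521, and Dppa5a, a naive marker, at 4342 and 3818. The list of LIF-STAT3 response genes had 9 of 16 members lower and 0 higher, with a median of −1.04 that none of the random lists reached, and it shares 5 members with other lists. Sgk1 stood at 1087 and 517, Klf4 at 889 and 314 and the kinase gene Jak3 at 392 and 150. Formative and primed pluripotency genes gave no common direction, with 2 of 7 higher and 2 lower and a median of 0.20 at percentile 79.3. Among them Dnmt3a stood at 58 and 134, Zic2 at 104 and 17 and Nodal at 176 and 71.

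**Figure D2:**
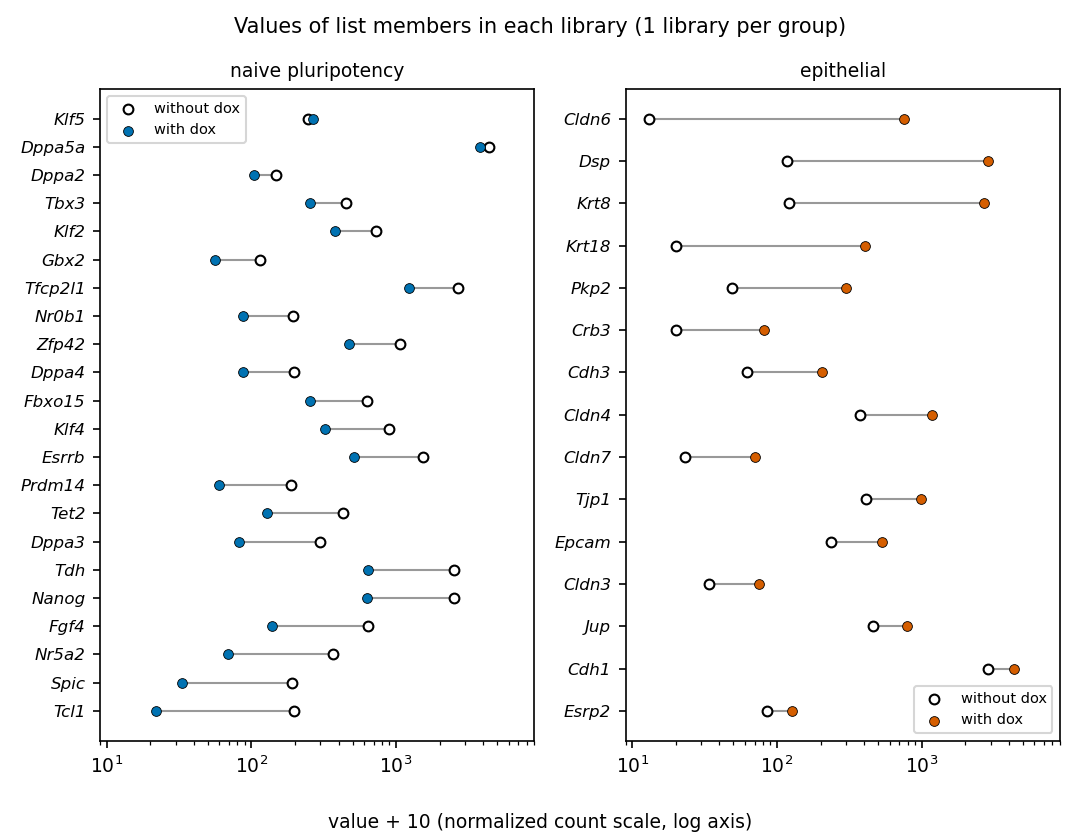
Values plus 10 (x axis, log scale, normalized count units) of the members of the naive pluripotency and epithelial lists (y axis), without dox (open circles) and with dox (filled circles), 1 library each, joined by a line. In the naive list 17 of 22 genes stand at least 2-fold lower with dox, and in the epithelial list 12 of 15 stand at least 2-fold higher.

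AP-1 and serum response target genes had the highest list median, 2.33, above those of all 10000 random lists. It was 1.73 with a pseudocount of 50, 1.64 with no floor and 3.07 with a floor of 250. Of 23 measured members 17 were higher with dox and 2 lower. Krt8, a keratin gene of simple epithelia, stood at 111 without dox and 2672 with dox, and the intermediate filament gene Vim at 499 and 1571. The lower members were the secreted phosphoprotein gene Spp1, at 2679 and 988, and the cyclin D1 gene Ccnd1, at 902 and 361. In the list of AP-1 subunits themselves 3 of 8 members were higher and 0 lower, with a median of 0.71 at percentile 99.5. Among these were Jun and Fosl2, the latter at 8 and 418. Of subunit genes chosen after their values were seen, Junb stood at 68 and 66, Jund at 346 and 570, and Fos, under the floor, at 2 and 1. Fosl1, at 0 and 33, and Atf3, at 7 and 45, were under the floor too but had larger values with dox.

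Epithelial junction and keratin genes were higher with dox, with 12 of 15 measured members higher, 0 lower and a median log2 ratio of 1.67. The desmosome gene Dsp stood at 108 and 2870, the claudin gene Cldn4 at 362 and 1175 and the tight junction gene Tjp1 at 400 and 982. The E-cadherin gene Cdh1, chosen after its values were seen, stood at 2876 and 4351. Integrin and focal adhesion genes had 14 of 25 members higher, 0 lower and a median of 1.13. The integrin beta 1 gene Itgb1 stood at 818 and 4342, the actinin gene Actn1 at 759 and 2505, and the filamin gene Flna at 1136 and 2504. Both medians lay above those of all 10000 random lists. With the trend on transcript length removed they were 1.85 and 0.98. Extracellular matrix genes had 9 of 20 members higher and 1 lower, with a median of 0.62 at percentile 99.99, which was 0.31 with the length trend removed, 0.29 with no floor and 0.94 with a floor of 250. Sparc stood at 768 and 2219 and the collagen gene Col18a1 at 304 and 900, while Spp1 was lower. Mesenchymal genes had 9 of 10 measured members higher and 0 lower, with a median of 1.66 above all 10000 random lists. The tropomyosin gene Tpm1 stood at 174 and 806 and the caldesmon gene Cald1 at 203 and 678. In this list 15 of the 25 genes were under the floor, which admits a gene on its larger value, and with no floor the median over 23 genes was 0.53. The transcription factor genes Snai1, at 27 and 17, Zeb1, at 47 and 48, and Twist1, at 12 and 2, were among those under the floor and were chosen after their values were seen. Zeb2, at 0 and 11, and Snai2, at 0 and 3, were also under the floor and had larger values with dox.

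**Figure D3:**
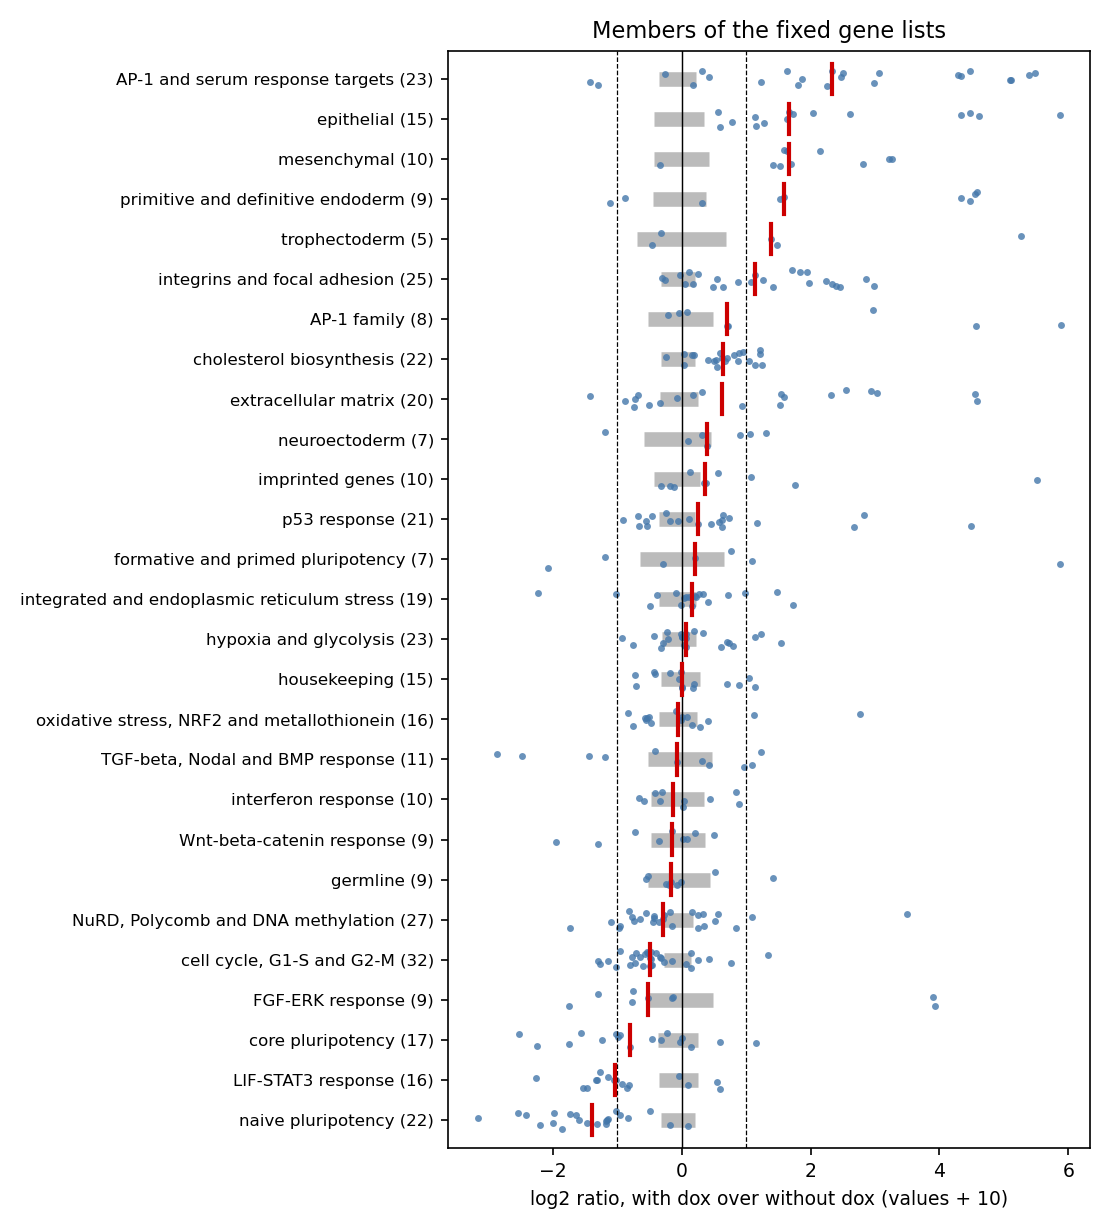
Log2 ratios, with dox over without dox, of the members (dots) of the 27 fixed gene lists with at least 5 members at or above the floor (y axis, number of members in brackets), with each list's median (red bar) and the range from percentile 2.5 to 97.5 of the medians of 10000 random lists matched on expression (grey bar). Dashed lines mark 2-fold; the median is −1.39 for naive pluripotency genes and 2.33 for AP-1 and serum response targets.

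Primitive and definitive endoderm genes had 6 of 9 measured members higher and 1 lower, with a median of 1.59 above all 10000 random lists. Of the 9 members, 8 also stood in other lists, and with no floor the median over 16 genes was 0.36. The laminin gene Lamb1 stood at 202 and 627 beside Krt8 and Sparc, and the apolipoprotein gene Apoe was lower, at 1007 and 458. The endoderm regulators Gata4, at 4 and 7, and Gata6, at 4 and 8, named after their values were seen, were under the floor. Trophectoderm genes had 3 of 5 members higher and 0 lower, with a median of 1.39 at percentile 99.9. Without Krt7, which was listed at 0 in the library without dox, the median over 4 members was 0.53. With no floor the median over 14 genes was 0.83. Tead4 stood at 50 and 158 and Ets2 at 76 and 215. Of genes under the floor, chosen after their values were seen, Cdx2 stood at 28 and 34, Eomes at 32 and 18, Hand1 at 0 and 17 and Ascl2 at 4 and 23. Neuroectoderm genes had 2 of 7 higher and 1 lower, with a median of 0.39 at percentile 96.2, which was 0.14 with the length trend removed. Nes stood at 55 and 151, Nefl at 129 and 279 and Tubb3 at 302 and 127. Only 2 mesoderm and primitive streak genes reached the floor, T at 121 and 24 and Cdx1 at 112 and 85. One of the 2-cell-like genes did, Eif1a, at 736 and 543. Of 22 fibroblast markers 2 reached the floor, Col5a1 at 20 and 220 and Col5a2 at 54 and 30. Of 7 blood and endothelial markers among the rows 4 reached it, and the macrophage-associated Csf1r and Cd68 were higher with dox, at 1 and 111 and at 19 and 96, while Pecam1 stood at 205 and 152 and Tek at 52 and 64.

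The cell cycle list had a median log2 ratio of −0.49, and 0 of the 10000 random lists had a median as low, while 27 of its 32 members were within 2-fold. The 4 members at least 2-fold lower were Ccnd1, the replicative helicase gene Mcm7, at 2056 and 921, the replication licensing gene Cdc6, at 261 and 102, and the mitotic kinase gene Aurka, at 393 and 189. The inhibitor gene Cdkn2b was higher, at 17 and 58. In the list of p53 response genes 4 of 21 members were higher and 0 lower, with a median of 0.25 at percentile 98.8, which was 0.51 with a floor of 250 and 0.39 with the length trend removed. Perp, a desmosome-associated target, stood at 17 and 600, the kinase genes Plk2 at 188 and 437 and Plk3 at 34 and 301, and Gadd45a at 20 and 181. Trp53 itself, chosen after its values were seen, stood at 1023 and 541.

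Of 22 cholesterol biosynthesis genes 5 were at least 2-fold higher with dox, 0 were lower and 17 were within 2-fold. The list median of 0.65 lay above those of all 10000 random lists. Msmo1 stood at 251 and 608, Cyp51 at 178 and 379 and Nsdhl at 61 and 155. Imprinted genes had 3 of 10 members higher and 0 lower, with a median of 0.36 at percentile 98.8, which became percentile 96.0 when the random lists were also matched on transcript length. Peg3 stood at 163 and 578 and the noncoding RNA gene Rian at 407 and 867, beside Peg10.

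The remaining signalling and stress lists had medians within the range of the random lists matched on expression. In the list of TGF-beta, Nodal and BMP response genes 2 of 11 members were higher and 4 lower, with a median of −0.08 at percentile 51.3. This median was −0.45 with the length trend removed and −0.41 without members of other lists, and the percentile was 10.4 with length matching. Lefty1 stood at 169 and 56 and Cyr61 at 71 and 179. FGF-ERK response genes had 2 of 9 higher and 2 lower, with a median of −0.53 at percentile 3.28 and a mean of 0.27, and the median was −0.32 with the length trend removed. Phlda1 stood at 9 and 275 and the feedback inhibitor gene Spry2 at 148 and 37, and the phosphatase gene Dusp5 was listed at 0 and 142. In the Wnt-beta-catenin list 2 of 9 members, T and Ccnd1, were lower and 0 higher, and the median of −0.15 became 0.02 without members of other lists. NuRD, Polycomb and DNA methylation genes had 2 of 27 higher and 2 lower, with a median of −0.29 at percentile 3.68, or 1.97 with length matching. The dioxygenase gene Tet3 was higher, at 20 and 328, and Tet1 and Tet2 were lower, at 1072 and 494 and at 419 and 119. Integrated and endoplasmic reticulum stress genes had 2 of 19 higher and 2 lower, with a median of 0.15 at percentile 94.3, or 98.6 with length matching. Ddit4 stood at 89 and 318, Trib3 at 41 and 132 and Psph at 95 and 42.

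Hypoxia and glycolysis genes had 3 of 23 members higher and 0 lower, with a median of 0.07, among them Ndrg1 at 119 and 292 and Bnip3 at 12 and 54. Oxidative stress, NRF2 and metallothionein genes had 2 of 16 higher, Srxn1 at 63 and 488 and Sqstm1 at 485 and 1072, with a median of −0.06 and a mean of 0.03. Germline genes had 1 of 9 higher, Prdm1 at 42 and 129, with a median of −0.16 and a mean of 0.02. Of 10 interferon response genes 0 passed 2-fold, with Ifitm1 at 591 and 600 and Ifitm2 at 557 and 416, and their median of −0.14 became 0.04 with the length trend removed. With no floor the Wnt-beta-catenin and interferon medians were 0.10 and 0.13, and with the median log2 ratio of all genes set to 0 the oxidative stress median was 0.02. Housekeeping genes had a median of 0.00, with 2 of 15 higher, Ywhaz at 1295 and 2676 and Gapdh at 6781 and 14907. The value of Gapdh lies on a step of the deposited scale. In each library 10 genes shared the highest value of 14907, and Lars2, Gm42418 and Gm38312 left that set with dox. Gapdh, Pabpc1 and Atp5b entered it from 6781, 6787 and 6781, which makes 2.20-fold, 2.19-fold and 2.20-fold. Among 27 lists with at least 5 measured members, 15 had medians outside percentiles 2.5 to 97.5, and 14 of them were also outside with length matching. Separate lists of unrelated genes would give 1.35 on average. These lists share members and hold genes of related function, so the 2 numbers make no test. The 95% bootstrap interval over members included 0 for 6 of the 15. It ran from −0.04 to 4.57 for AP-1 subunits, −0.88 to 4.55 for endoderm, −0.46 to 5.26 for trophectoderm and −0.43 to 1.95 for extracellular matrix genes. For p53 response and imprinted genes it ran from −0.25 to 0.63 and from −0.12 to 1.16.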

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

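The length trend and the omission of genes at 0 were tried only after the data were seen. Counts of genes moved by more than 1.5 times under 5 alternatives. Genes at least 2-fold higher with dox numbered 498 with a pseudocount of 50, 1255 with no floor and 298 with a floor of 250, and those lower numbered 171, 796 and 147. At 1.5-fold 1425 were higher and 1511 lower, and at 4-fold 266 and 55, as thresholds do by construction. The log2 ratio of Jun was 5.20 with a pseudocount of 50. Of list medians, that of AP-1 and serum response targets, 2.33, was 1.73 with a pseudocount of 50, 1.64 with no floor and 3.07 with a floor of 250. That of mesenchymal genes, 1.66, was 1.498 with a pseudocount of 50 and 0.53 with no floor. The endoderm median, 1.59, was 0.36 with no floor, and the trophectoderm median, 1.39, was 0.53 without genes at 0. A floor admits more or fewer genes by construction; for the others the cause was not tested. Setting the median log2 ratio to 0 gave 875 and 374 genes, scaling to the same total 775 and 469, a pseudocount of 1 879 and 608, omission of genes at 0 751 and 467, and removal of the length trend 737 and 425. Of the list medians under all alternatives 229 stayed within 1.5-fold and within the main 95% bootstrap interval over members and 7 did not. Those intervals are wide for lists of few members, and they and 1.5-fold are loose bounds for medians near 0, several of which changed sign. No median that lay outside percentiles 2.5 to 97.5 changed sign. Scaling to the same total and setting the median log2 ratio to 0 could shift a log2 ratio only slightly, and moved no result past these bounds. The sums were already near equal and the median log2 ratio was −0.08, so these 2 alternatives say little about the stability of large ratios. Counts near the threshold did respond: with the median set to 0, genes called lower went from 469 to 374 and those called higher from 789 to 875. Of the values of single named genes 117 stayed within 1.5-fold and 28, all under the pseudocounts of 1 or 50, did not. With a pseudocount of 1, 11 moved and 18 did not, and with 50, 17 moved and 12 did not. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. The depth behind each value is unknown.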

Other observations

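Gene families were formed from the stems of gene symbols after the data were seen, and so were the tests of mitochondrial tRNA synthetase genes, ribosomal RNA, fibroblasts and keratinocytes below. The tests of the transcript length trend and of its effect on the lists were set before their results were seen. Of 130 families with at least 8 measured members, 29 had median log2 ratios outside percentiles 2.5 to 97.5 of matched random lists, and 23 did with length matching. The keratin genes stood highest, with 8 of 9 higher with dox and a median of 4.47. They included genes of stratified epithelia: Krt16 stood at 4 without dox and 281 with dox, Krt17 at 4 and 109, and Krt5 and Krt6a were listed at 0 and at 226 and 303. Among symbols with the stem Col, of which Col4a3bp is not a collagen gene, 7 of 10 were higher, with a median of 3.04. The floor admits a gene on its larger value, which left out 17 such genes low in both libraries, and with no floor the median over 27 was 0.51. The basement membrane genes Col4a1 and Col4a2 stood at 12 and 507 and at 2 and 278. Annexin genes, which encode membrane-binding proteins, had 6 of 8 higher and a median of 2.40, with Anxa2 at 27 and 1249 and Anxa5 at 15 and 455. Dual-specificity phosphatase genes (Dusp), several of which encode MAP kinase inhibitors, had 8 of 12 higher, 1 lower and a median of 1.99, with Dusp1 at 113 and 610, Dusp14 at 82 and 439 and Dusp9 at 72 and 286. With no floor the medians were 4.38 over 11 keratin genes, 1.82 over 9 annexin genes and 1.03 over 19 Dusp genes. Myosin genes had 6 of 13 higher and a median of 0.79, which was 0.46 with the length trend removed.

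Of the families with low medians a few are given here. Symbols with the stem Mcm, of which Mcm3ap is not an Mcm family gene, had a median of −0.65 over 10 members. Of these, 1 was at least 2-fold lower and 0 were higher. Mitochondrial ribosomal protein genes had medians of −0.51 over 46 large subunit members (Mrpl) and −0.52 over 28 small subunit members (Mrps), of which 0 and 2 were at least 2-fold lower. With the length trend removed these medians were −0.33 and −0.41. Zinc finger genes with the stem Zfp had a median of −0.32 over 202 members, with 25 lower and 2 higher. Small nucleolar RNA host genes (Snhg) had 4 of 10 lower and 1 higher, with a median of −0.64 that lay at percentile 0.47, or 3.34 with length matching, and −0.35 with the length trend removed. Medians per chromosome ran from −0.21 over 432 genes of chromosome 17 to 0.01 over 291 genes of chromosome 19.

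The log2 ratio rose with transcript length, from a median of −0.39 in the tenth of genes with the shortest transcripts (median 1105 nt) to 0.20 in the tenth with the longest (median 8665 nt). Spearman's rho across 8472 genes was 0.27 (95% bootstrap interval over genes 0.25 to 0.29), against 0.02 for GC content. The changed and listed genes alone are argued against as its source, since rho was 0.263 among 6983 genes that were within 2-fold and in no list. Recovery of transcripts that depends on their length, such as a difference in RNA integrity or fragment size between the libraries, is a candidate explanation. Within 202 Zfp genes rho was 0.260 (0.142 to 0.387), so the trend also held inside a single gene family. A trend across all genes would give such a value whatever its source, so this cannot tell recovery from other sources. A response to dox that itself depends on length was not tested and stays open with 1 library per group.

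Lars2, Gm42418 and Gm26917, which are known to collect ribosomal RNA reads, had log2 ratios of −4.51, −3.41 and −1.96. A joint fall of mitochondrial tRNA synthetase genes is argued against as the reason for Lars2, since the other 12 such genes had a median of −0.34 (−0.62 to −0.03). Less ribosomal RNA carried into the library with dox may account for them, but 0 ribosomal RNA genes were among the rows, so this cannot be told apart from a change in these genes. Gm38312 on chromosome 1 (89097073 to 89098818), at 14907 and 3246, was lower too, as were Gm37697, at 1497 and 456, and Cmah, at 4351 and 1396, whose transcripts share 1710 nt at 87.1% and 1678 nt at 82.7% identity with it. D10Wsu102e, which shares 1713 nt at 84.7% with it, stood at 207 and 164, and Dcaf13, which shares 1438 nt at 77.4%, at 226 and 210, both within 2-fold.

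Keratin, junction and adhesion genes were higher with dox. The length trend is argued against as the whole source, since with it removed the smaller of the epithelial and integrin list medians was 0.977. Fibroblasts in the culture as the main source are argued against by their most abundant collagen transcripts. Col1a1, Col1a2 and Col3a1 stood at 3, 19 and 39 with dox against a median of 417.5 over the 40 epithelial and integrin members. Col3a1, at 2 without dox, was only just under the limit set for this comparison. The comparison is also rough, since it sets different genes side by side on a scale taken to reflect ranks within classes. Of the other fibroblast markers that reached the floor, Col5a1 went from 20 to 220 and Col5a2 from 54 to 30, so a small share of fibroblasts stays open. Keratinocytes as a source of the simple keratins stay open: Krt5 stood at 226 with dox, below Krt8 at 2672, Krt18 at 395 and Krt19 at 474, but not far enough below on this scale to decide. A response of the cells to dox or to c-Jun is a hypothesis that these 2 libraries cannot test. Replicate cultures, and dox given to cells without an inducible c-Jun, would bear on it, and other differences between the cultures or library preparations stay open too.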
